A study of Mus musculus with 15 samples.

How the data were processed

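Total RNA of mouse ES cells and of the embryoid bodies named EB9 was labelled with Cy3, from 500 ng per sample per the labels, and hybridised to Agilent 1-colour whole-genome arrays. The 15 arrays fell into 4 groups by their labels: Cbx7 knockdown ES cells (4 arrays), control ES cells (3), Cbx7 knockdown EB9 (4) and control EB9 (4). The knockdown used 1 hairpin, named 33 in the labels. The choices of model, filter, gene lists, naming rule and alternatives were fixed before the data were examined, except for the alternatives named below as added.

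The authors extracted each scan with Agilent Feature Extraction 10.7.3.1, and the deposited scanner output holds intensity values per the file headers. The processed signal used here is an intensity corrected for background and for spatial trends within the array by that software, and it is not scaled between arrays. The deposited table of the authors holds log2 values, quantile normalised between arrays. Its background correction is not given in the sources used here; from the values, normexp correction with an offset of 50 followed by quantile normalisation gave the same numbers within 0.000154. Each array had 44397 features, of which 43020 were not controls. The 75th percentile of the processed signal ranged from 1483.2 in ES knockdown 4 to 2531.1 in EB9 control 2, and the mean of the negative controls from 34.27 to 42.88. No feature was saturated. For arrays the number of samples limits the precision.

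Slides and positions were read from the headers. The arrays lay on 4 slides. EB9 control arrays took position 1, EB9 knockdown position 2, ES control position 3 and ES knockdown position 4. The slide number equalled the replicate number except for ES controls 2, 3 and 4, which lay on slides 1, 2 and 3. Whether numbers pair the samples was checked with each array's deviations from its group mean. Arrays of different groups on the same slide correlated at a median of 0.43 (21 pairs, 0.21 to 0.63, across genes). ES controls correlated at a median of −0.34 with arrays of the same replicate number (9 pairs, −0.59 to 0.37). With those of the same slide the median was 0.44 (9 pairs, 0.21 to 0.63). Both the slide and the number were therefore tried as the block of an alternative fit, and the slide is the one given beside the results. This reading takes the numbers of the ES controls as the labels give them; if they were shifted by 1, slide and number would be the same.

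The processed signal was log2-transformed, and the 75th percentile of the non-control features of the array was subtracted. Between 109 and 179 features per array that the software flagged as non-uniform or as population outliers were left out, and repeated spots of a probe were averaged, giving 39429 probes. Probes were named by RefSeq accession (26424), current symbol (3983), unique older symbol (826) or else the name in the file (8196), which gave 30818 names. A probe was kept where it was well above background, by the software's own test, on at least 3 arrays of a group (27248 probes). Each gene was then represented by its brightest probe over all 15 arrays, which left 21180 genes, 75 of them with a missing value. Coordinates are those of the probe in the files (build mm9). Where no array of the dimmer group lay well above background, a fold is a lower bound, computed against the lowest signal still well above background on each array.

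Differences were tested with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8), with a mean per group over all 15 arrays (11 residual and 1.61 prior degrees of freedom), empirical Bayes moderation and two-sided tests. The comparisons were knockdown against control in ES cells and in EB9, EB9 against ES cells in control and in knockdown, and the difference of the knockdown effect between EB9 and ES cells. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene passed at an adjusted p under 0.05. The Cbx7 probes were tested in the same model fitted to all kept probes, and their p-values were adjusted over those probes. An SE is the moderated SE of a log2 difference, and an SD is that of a group's arrays. The count of genes that passed in both knockdown comparisons was set beside the count that independent lists would share.

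The 24 gene lists covered Polycomb subunits, pluripotency, primed epiblast, primitive streak and early mesoderm, cardiac muscle, skeletal and smooth muscle, visceral endoderm, parietal endoderm, neuroectoderm and neurons, surface ectoderm, trophoblast, blood, endothelium, fibroblasts and mesenchyme, Hox genes, developmental transcription factors, Ink4-Arf and other inhibitors of cyclin-dependent kinases, cell proliferation, p53 targets, interferon response, immediate early genes, germ line, 2-cell genes, and hypoxia and glycolysis. Some genes stand on more than 1 list. Each list was tested against all other genes with limma's camera at a preset correlation between genes of 0.01, two-sided, and adjusted over the lists within a comparison. No list passed in any comparison when camera estimated the correlation from the data. That correlation came from the fit without the slide as a block, so the slide effect can enter it, and it was not estimated with that block. In this setting even pluripotency genes in control EB9 against ES cells did not pass (29 of 32 lower, median −3.69, adjusted p = 0.179). A list lost in this setting is thus not shown to be unchanged. The alternative test fry asks whether the genes of a list move on balance one way and does not compare them with other genes.

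Genes were named by a rule. In each comparison it took Cbx7, then the 10 greatest rises and 10 greatest falls among genes that passed, whose groups did not overlap and whose probe was well above background on every array of the brighter group, leaving out names that are not official symbols. For the difference of the effect it took 5 each way with no overlap criterion. It added up to 4 members of each list that passed (the 2 greatest rises and 2 greatest falls among members past the threshold) and the Polycomb members past the threshold. Not every gene given by the rule is printed.

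The procedure was tested on simulated data of the same design with 21105 genes, 230 of them changed. Of these 200 were spread over 4 sizes, 50 per size, and 30 formed a gene list raised by 0.5. At log2 sizes of 0.5, 1, 2 and 4 the fit recovered 62%, 80%, 88% and 100% in the ES comparison, 54%, 86%, 90% and 100% in EB9, 52%, 74%, 88% and 100% in the control stage comparison, 54%, 80%, 94% and 100% in the knockdown stage comparison, and 28%, 62%, 88% and 96% for the difference of the effect. Between 4.3% and 7.1% of the calls were false. The simulated genes varied independently of each other and carried no slide effect. The real arrays had a slide effect and far more calls, so these shares need not hold for them.

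The alternatives were quantile normalisation, median scaling, normexp background correction (offset 50), the authors' table, no filter on dim probes, a filter for probes well above background on every array of a group, the mean of each gene's probes, a fit of the compared groups alone, the replicate number as a block, the slide as a block, array weights, an adjusted p under 0.01, at least 2-fold changes, the estimated correlation and fry for the lists, and leaving out each array in turn. A fit of slides 1 to 3 alone and the slide block together with a 2-fold minimum were added after the slide effect was seen. For each comparison the arrays were also regrouped in all 35 splits of the same sizes, or in 100 drawn splits for the difference of the effect and the overlap. The 8 regroupings of each of the first 4 comparisons that swap arrays only within slides were added after the slide effect was seen.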

Results

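Gene expression was measured by 1-colour microarray in mouse embryonic stem (ES) cells and in embryoid bodies made from them, each carrying either a control short hairpin RNA or hairpin 33 against Cbx7. Cbx7 is a chromodomain protein that belongs to the canonical form of Polycomb repressive complex 1, which keeps developmental genes silent. EB9 is the labels' name for the embryoid bodies, three-dimensional aggregates in which ES cells differentiate. The 15 arrays comprised 4 of Cbx7 knockdown ES cells, 3 of control ES cells, 4 of Cbx7 knockdown EB9 and 4 of control EB9, all named biological replicates. Between 62.5% and 69% of the features of an array lay well above background, and 75.4% on EB9 control 2. No feature was saturated, and 21180 genes were tested. The number of arrays limits the precision, and p-values weigh a difference against the spread between the arrays of a group. Where no slide term was fitted, that spread includes differences between slides. With 1 hairpin it holds no variation between hairpins. The arrays of each group sat at 1 fixed position on each of 4 slides, so position and group cannot be told apart, and slide 4 held no ES control.

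The transcript targeted by the hairpin was measured by 2 probes. Probe A_55_P1980401 (mm9 chromosome 15, 79746240 to 79746299) read −4.16 ± 1.85 (SD, n = 3) in control ES cells and −6.07 ± 1.79 (n = 4) in knockdown ES cells, in log2 units relative to the 75th percentile of the array. The difference of −1.91 (SE 1.23) had an adjusted p of 0.256, and this probe lay lower on slides 1 and 4 than on slides 2 and 3 in every group. Within slides the probe was lower in knockdown ES cells by −1.56, −1.3 and −1.57 on slides 1, 2 and 3. A model with a term for the slide gave −1.41 (SE 0.17, adjusted p = 9.99e-05). The probe was well above background on 3 of 3 control but on 2 of 4 knockdown ES arrays, so the size of the difference is uncertain. Without the slide term it was −0.61 with normexp background correction and −0.8 with the authors' values. In EB9 the same probe differed by −0.27 (SE 1.14, adjusted p = 0.92), or by −0.31, −0.36, −0.52 and 0.12 on the 4 slides, and with the slide term its adjusted p was 0.221. It was well above background on 2 of 4 control and 2 of 4 knockdown EB9 arrays. From control ES cells to control EB9 it was lower by −2.76 (SE 1.23, adjusted p = 0.058), which became −2.26 (adjusted p = 4.61e-07) with the slide term. With that term the knockdown effect on it differed between EB9 and ES cells by 1.14 (SE 0.23, adjusted p = 0.00302), against 1.64 (SE 1.68, adjusted p = 0.534) without it. The other probe A_55_P1980408 (chromosome 15, 79748605 to 79748664), which the files assign to a cDNA clone and not to the RefSeq transcript, differed by −0.13 (SE 0.23, adjusted p = 0.733) in ES cells and by −0.16 (SE 0.22, adjusted p = 0.708) in EB9, and the slide term left both differences short of the threshold (adjusted p = 0.868 and 0.36). This other probe was well above background on 3 of 3 control and 4 of 4 knockdown ES arrays and on 4 of 4 arrays of each EB9 group. Its differences within slides were 0.11, −0.15 and −0.15 in ES cells and −0.36, −0.3, −0.23 and 0.26 in EB9. Fitted with no slide term and leaving out 1 array at a time, the difference of the first probe ran from −2.98 (without ES control 2) to −1.31 (without ES knockdown 1) in ES cells. In EB9 it ran from −0.86 (without EB9 control 4) to 0.24 (without EB9 control 3), so its sign there hung on 1 array. That of the other probe ran from −0.38 to 0 in ES cells and from −0.34 to −0.04 in EB9, with ES control 2 or 3 and EB9 control 4 or 3 left out.

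**Figure D1:**
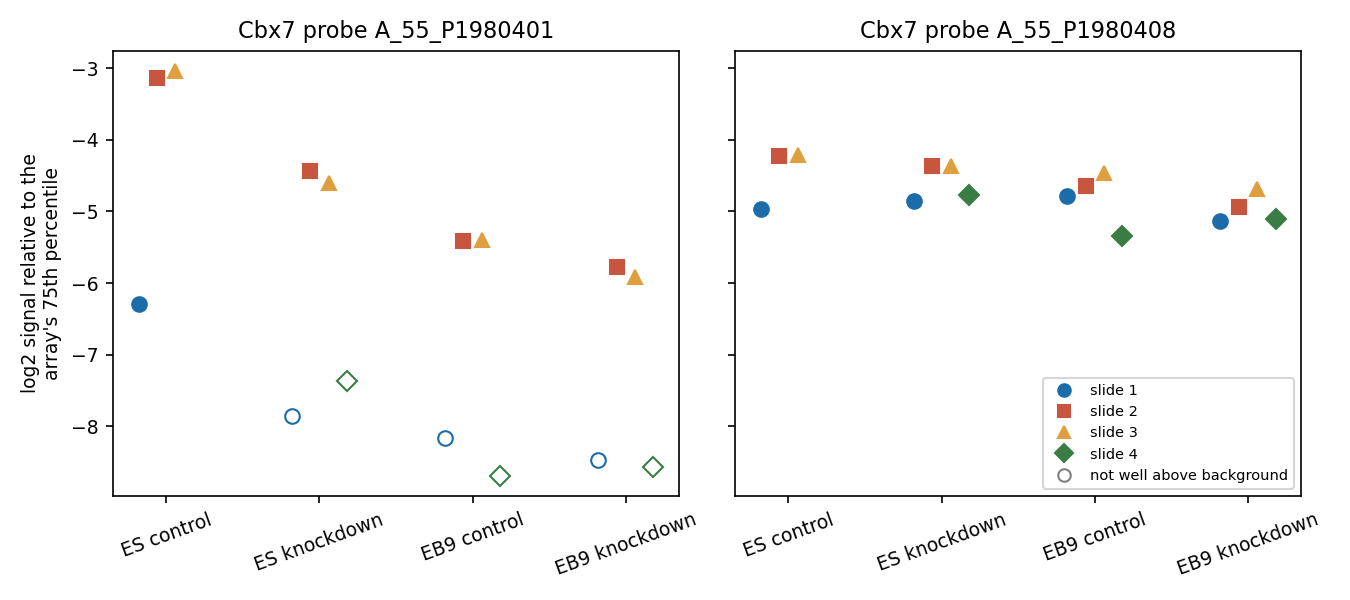
Level of Cbx7 on each array, as log2 signal relative to the 75th percentile of the array, for both probes; each symbol is 1 array, coloured by slide, and open symbols were not well above background. With probe A_55_P1980401 the knockdown ES array lay below the control ES array on each of slides 1 to 3, while slides 1 and 4 lay below slides 2 and 3 in every group.

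The comparison of Cbx7 knockdown with control ES cells asks which transcripts differ in undifferentiated cells that carry the Cbx7 hairpin. Transcription factors of embryonic development rose as a group: of 90 measured members 42 were higher and 6 lower, with a median change of 0.45 on the log2 scale (adjusted p = 0.463 with an estimated correlation between genes). Hox genes, which pattern the body axis, rose with them (20 higher and 2 lower of 37, median 0.7; adjusted p = 0.463 with an estimated correlation). Ccnd2, which encodes cyclin D2 (probe A_52_P53906, chromosome 6, 127098696 to 127098755), rose 6.86-fold, from −3.28 ± 0.08 (SD, n = 3) to −0.5 ± 0.04 (n = 4; log2 change 2.78, SE 0.07, adjusted p = 2.67e-10). The X-linked gene Xlr4b (probe A_55_P2046101, chromosome X, 70467477 to 70467536) fell from 1.1 ± 0.1 to −2.7 ± 0.1 (log2 change −3.8, SE 0.31, adjusted p = 1.48e-06). In all, 8147 genes passed the threshold, 4654 higher and 3493 lower, and 1039 of them changed at least 2-fold, 373 upwards and 666 downwards.

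Among the genes with the greatest changes, Xlr5b fell by 4.13 (SE 0.55) and Xlr4a by 3.86 (SE 0.33). Bfsp2, a filament protein of the eye lens, fell by 4.03 (SE 0.37), and the olfactory receptor gene Olfr1466 changed by −4.55 (SE 0.5, adjusted p = 1.72e-05). Dnajc5g, a member of the cysteine string protein family, was at least 6.07-fold lower. A fold is given as "at least" where no array of the dimmer group lay well above background; it was computed against the level the measurement could still have told from background. Dio3, the deiodinase that inactivates thyroid hormone (chromosome 12, 111518792 to 111518851), rose 4.25-fold (log2 change 2.09, SE 0.1, adjusted p = 2.77e-08). Twist2, a mesenchymal transcription factor, was at least 2.06-fold higher, the cell adhesion molecule Alcam at least 3.26-fold and Prdm8, a regulator of neural development, at least 1.62-fold.

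The developmental transcription factors passed the set test against all other genes (adjusted p = 0.000879; 44 higher and 6 lower when adjusted over the list alone). With an estimated correlation between genes their adjusted p was 0.463. Zic1, a regulator of neural fate, rose 3.19-fold (log2 change 1.68, SE 0.22) and Olig2, a regulator of oligodendrocyte and motor neuron fate, was at least 2.93-fold higher. Meis2, a cofactor of Hox proteins, went the other way and fell by 1.7 (SE 0.1, adjusted p = 1.1e-07). The Hox genes passed as well (adjusted p = 0.00144; 21 higher and 2 lower adjusted over the list alone; adjusted p = 0.463 with an estimated correlation). Hoxd4 rose 2.88-fold (log2 change 1.52, SE 0.21), whereas Hoxb13 fell by 0.46 (SE 0.08). Markers of neuroectoderm and neurons, some of them also on the list of transcription factors, rose (14 higher and 1 lower of 24, 15 and 1 adjusted over the list alone, median 0.62, adjusted p = 0.00565; adjusted p = 0.748 with an estimated correlation). Pou3f2, a neural transcription factor of this list, rose by 2.06 (SE 0.59, adjusted p = 0.0142), a call that was lost without ES control 3, where the change was 1.96.

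2 groups fell in knockdown ES cells. Targets of p53, the transcription factor of the DNA damage response, were lower (10 lower and 1 higher of 19, 10 and 2 adjusted over the list alone, median −0.42, adjusted p = 0.00155; adjusted p = 0.102 with an estimated correlation). Ccng1 fell by 0.95 (SE 0.06) and Phlda3 by 1.04 (SE 0.06), while the pro-apoptotic Bax rose by 0.42 (SE 0.1). Of 12 markers of parietal endoderm 5 fell and none rose, also when adjusted over the list alone (median −0.24, adjusted p = 0.00565; adjusted p = 0.463 with an estimated correlation), among them the basement membrane collagen Col4a1 by 0.79 (SE 0.06) and the proteoglycan gene Srgn by 1.14 (SE 0.32). The Polycomb subunits did not pass as a list (4 higher and 6 lower of 32, median −0.05, adjusted p = 0.381), although they were lower with fry (0.0143). Of its members Suz12, a core subunit of Polycomb repressive complex 2, fell by 0.62 (SE 0.06), Rybp by 0.48 (SE 0.05) and Bmi1 by 0.46 (SE 0.06), and Phf19 rose by 0.71 (SE 0.12).

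The other lists did not pass in ES cells. Pluripotency genes gave 5 higher and 9 lower of 32 (median −0.11, adjusted p = 0.381). Primed epiblast markers gave 5 higher and 1 lower of 12 (0.381), primitive streak and early mesoderm 2 higher and 4 lower of 17 (0.381), immediate early genes 3 higher and 6 lower of 19 (0.186) and cell proliferation 13 higher and 2 lower of 32 (0.254). With fry primed epiblast (0.00692), immediate early genes (0.00382) and cell proliferation (0.0143) passed. The remaining adjusted p-values were 0.965 for cardiac muscle, 0.839 for skeletal and smooth muscle, 0.734 each for visceral endoderm, surface ectoderm, blood, endothelium, fibroblasts and hypoxia, 0.847 for trophoblast, 0.477 for Ink4-Arf and the other inhibitors of cyclin-dependent kinases, 0.446 for the germ line and 0.536 for 2-cell genes. The interferon list gave 1 higher and 2 lower of 22 (median −0.03, mean 0.01). Median and mean also differed in sign for skeletal and smooth muscle (0.13 and −0.02), visceral endoderm (0.01 and −0.16), surface ectoderm (0.04 and −0.05) and endothelium (0.07 and −0.06), all tested downwards.

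With the slide term 10058 genes passed in ES cells, and 8018 of the 8147 kept their call; array weights gave 14011. With normexp background correction or the authors' values, which compress low signals, 321 or 339 genes changed at least 2-fold. The changes within slides 1, 2 and 3 correlated with each other at 0.769 to 0.787 across all genes, which are not independent replicates. The groups did not overlap for 49.6% of all genes, where chance gives 5.7%.

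The comparison of knockdown with control EB9 asks which transcripts differ in the differentiated aggregates that carry the hairpin; neither Cbx7 probe was past the threshold in EB9. Genes of the primitive streak and early mesoderm fell (10 lower and none higher of 17, median −0.89; adjusted p = 0.151 with an estimated correlation). Brachyury (T), the transcription factor that specifies mesoderm (probe A_55_P2029161, chromosome 17, 8635302 to 8635361), fell 6.93-fold, from −1.92 ± 0.7 (SD, n = 4) to −4.71 ± 0.77 (n = 4; log2 change −2.79, SE 0.36, adjusted p = 0.000483). Genes of hypoxia and glycolysis rose (15 higher and none lower of 24, median 0.52; adjusted p = 0.125 with an estimated correlation). Hox genes fell (8 lower and none higher of 37, median −0.33; adjusted p = 0.151 with an estimated correlation). The cell cycle inhibitors of the Ink4-Arf locus rose: Cdkn2b (chromosome 4, 88952276 to 88952335) by 0.97 (SE 0.12, adjusted p = 0.000432) and Cdkn2a (chromosome 4, 88920405 to 88920464) by 0.73 (SE 0.11, adjusted p = 0.000991). In knockdown ES cells Cdkn2a also rose, by 0.49 (adjusted p = 0.00483), whereas Cdkn2b fell there by 0.45 (adjusted p = 0.0176). In all, 3211 genes passed, 1686 higher and 1525 lower, and 294 changed at least 2-fold, 150 upwards and 144 downwards.

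The imprinted gene Mest (probe A_51_P124535, chromosome 6, 30698279 to 30698338) fell 4.86-fold, from 2.95 ± 0.25 to 0.66 ± 0.09 (log2 change −2.28, SE 0.1, adjusted p = 1.19e-07). Cer1, a secreted inhibitor of Nodal, Wnt and BMP signals, was at least 2.83-fold lower and Pax1, a transcription factor of the sclerotome, at least 2.11-fold lower. The lipoxygenase gene Alox15 fell 5.71-fold (log2 change −2.51, SE 0.32), Xlr4b 7.56-fold (−2.92, SE 0.28) and Xlr3b 4.01-fold (−2, SE 0.24). Stra8, a gene of the entry into meiosis (chromosome 6, 34889237 to 34889296), rose 3.2-fold, from −1.84 ± 0.34 to −0.16 ± 0.19 (log2 change 1.68, SE 0.14, adjusted p = 4.83e-05). Stmn4, a neuronal stathmin, rose 3.08-fold (1.62, SE 0.14) and Nts, the neurotensin precursor, 3.11-fold (1.64, SE 0.25).

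The hypoxia and glycolysis list had the lowest adjusted p of the set test in EB9 (3.5e-12; 17 higher and 1 lower adjusted over the list alone; adjusted p = 0.125 with an estimated correlation). Ero1a, an oxidase of the endoplasmic reticulum, rose 2.01-fold (log2 change 1.01, SE 0.09) and Ankrd37 by 0.85 (SE 0.09). For the primitive streak list the adjusted p was 2.55e-06 (2 higher and 11 lower adjusted over the list alone; adjusted p = 0.151 with an estimated correlation), and for the Hox genes it was also 2.55e-06 (0 higher and 11 lower over the list alone; adjusted p = 0.151 with an estimated correlation). Hoxb9 fell by 1.36 (SE 0.23). Immediate early genes, which respond to serum and stress, rose (8 higher and 1 lower of 19, 10 and 1 adjusted over the list alone, median 0.37, adjusted p = 7.61e-06; adjusted p = 0.125 with an estimated correlation), Ier3 by 0.82 (SE 0.09) and Junb by 0.63 (SE 0.1). Visceral endoderm markers fell (9 lower and none higher of 24, 11 and 1 over the list alone, median −0.42, adjusted p = 0.00107; adjusted p = 0.493 with an estimated correlation), with Cubn, the cubilin receptor, lower by −1.28 (SE 0.3); the list was lost with fry (0.0603). The interferon list passed (adjusted p = 7.61e-06, median 0.87; adjusted p = 0.493 with an estimated correlation) on few members: 2 of 22 were higher, 5 when adjusted over the list alone, and none was lower, and it was lost with fry (0.0542). The members were Oas1a (1.16, SE 0.34, adjusted p = 0.0352) and Gbp2 (0.53, SE 0.16, adjusted p = 0.0417), and neither kept its call without EB9 knockdown 1 (0.95 and 0.42), 3 (1.13 and 0.58) or 4 (1.12 and 0.52), or without EB9 control 3 (1.04 and 0.41) or 4 (1.06 and 0.43). Oas1a also lost it without EB9 control 2 (1.03), and Gbp2 without any 1 of the 7 ES arrays (0.53 each).

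Further lists passed in EB9 with small medians. Germ line genes were higher (6 higher and 1 lower of 20, the same over the list alone, 0.34, adjusted p = 0.00647; 0.493 as the adjusted p with an estimated correlation), with Stra8 above and Tuba3a lower by −0.61 (SE 0.1). Cell proliferation genes fell (6 lower and none higher of 32, 7 over the list alone, −0.08, adjusted p = 0.00608; adjusted p = 0.458 with an estimated correlation), among them the mitotic kinase Plk1 by 0.33 (SE 0.07). Primed epiblast markers fell (5 lower and 1 higher of 12, 6 and 1 over the list alone, −0.39, adjusted p = 0.0184; adjusted p = 0.367 with an estimated correlation), Fgf15 by 1.07 (SE 0.17), and were lost with array weights (0.0525). Pluripotency genes were higher (11 higher and 4 lower of 32, 13 and 4 over the list alone, 0.14, adjusted p = 0.00745; adjusted p = 0.551 with an estimated correlation), with Dppa3 up by 1.06 (SE 0.15) and Tbx3 down by −0.76 (SE 0.15). The list was lost without EB9 knockdown 2 (adjusted p = 0.205) or EB9 control 1 (0.0629), with array weights (0.055) and with fry (0.0893). Endothelial markers fell (5 lower and none higher of 18, 6 over the list alone, −0.2, adjusted p = 0.014; adjusted p = 0.325 with an estimated correlation), Etv2, a regulator of blood and vessel progenitors, by 0.99 (SE 0.16). It was lost without EB9 knockdown 2 (0.159) or EB9 control 4 (0.0523) and with array weights (0.055). The Ink4-Arf list was higher (3 higher and 1 lower of 7, 4 and 1 over the list alone, 0.23, adjusted p = 0.037; adjusted p = 0.247 with an estimated correlation), with Cdkn1c going down by −0.62 (SE 0.13). This call was lost without EB9 knockdown 2 (0.184) or EB9 control 2 (0.0609), with normexp background correction (0.0855), with the authors' values (0.0538), with the mean of each gene's probes (0.538) and with array weights (0.0905).

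Trophoblast markers lay at the threshold in EB9 (1 higher and 6 lower of 15, 2 and 7 over the list alone, median −0.23, adjusted p = 0.0482; adjusted p = 0.493 with an estimated correlation). Rhox6 fell by 1.14 (SE 0.24) and Ascl2 rose by 0.41 (SE 0.08). The list was lost with the slide term (0.122), with array weights (0.0559), without the filter on dim probes (0.121) and in a fit of the EB9 arrays alone (0.0816). It was also lost without ES knockdown 2 (0.0541), 3 (0.0528) or 4 (0.0517), ES control 2 (0.055) or 4 (0.0504), EB9 knockdown 1 (0.101) or 3 (0.0697), or EB9 control 1 (0.061), 2 (0.0722), 3 (0.0514) or 4 (0.0523). Skeletal and smooth muscle markers did not pass (0 higher and 1 lower of 16, adjusted p = 0.0526) but did with the slide term (0.0349), in a fit of the EB9 arrays alone (0.04), with the mean of each gene's probes (0.0477), and without ES knockdown 1 (0.0474), ES control 2 (0.0469) or EB9 control 2 (0.0484) or 4 (0.047). The 2-cell genes did not pass (0 higher and 1 lower of 12, adjusted p = 0.128) but did without EB9 control 1 (0.00695). The developmental transcription factors gave 10 higher and 14 lower of 90 (13 and 14 over the list alone, adjusted p = 0.634), and the adjusted p was 0.961 for cardiac muscle and for neuroectoderm, 0.849 for parietal endoderm, 0.464 for surface ectoderm and for p53 targets, and 0.681 for blood and for fibroblasts. The median and the direction of the test differed in sign for blood (0.08, tested downwards), neuroectoderm (−0.07, upwards) and cardiac muscle (−0.04 against a mean of 0.01, upwards).

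Of 32 Polycomb subunits 3 were higher and 2 lower in EB9 (median 0.02, adjusted p = 0.85). Bmi1 fell by 0.26 (SE 0.06, adjusted p = 0.00984). Phc3 rose by 0.44 (SE 0.11) and Jarid2 by 0.43 (SE 0.1), and Suz12 fell by 0.21 (SE 0.06). The calls of Phc3, Jarid2 and Suz12 were lost without EB9 knockdown 4 (0.4, 0.38 and −0.21). That of Suz12 was also lost without EB9 knockdown 1 (−0.18) or EB9 control 2 (−0.17), 3 (−0.2) or 4 (−0.22), and that of Phc3 without EB9 knockdown 3 (0.37) or EB9 control 3 (0.38).

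With the slide term 5663 genes passed in EB9, 3195 of the 3211 among them. In a fit of the EB9 arrays alone 1133 passed, and of the genes named for EB9 the calls of Oas1a, Gbp2, Cubn, Tbx3, Cdkn1c, Plk1, Rhox6, Ascl2, Bmi1, Phc3, Jarid2 and Suz12 were lost at unchanged log2 values. EB9 control 2 lay apart from the other EB9 controls on the first principal component (98.8 against 122.5 to 131). Without it 2990 genes passed, 1780 higher and 1210 lower, with 12 lists. Without EB9 knockdown 4 or 3 or EB9 control 4 the count was 1807, 1898 or 2035, and median scaling gave 1398, array weights 6481 and slides 1 to 3 alone 674. At least 2-fold changes numbered 80 with normexp background correction or the authors' values, 164 in the fit of the EB9 arrays alone, 572 with array weights and 125 on slides 1 to 3. The changes within the 4 slides correlated with each other at 0.166 to 0.641 across all genes, and the groups did not overlap for 15.7% of all genes, where chance gives 2.9%.

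**Figure D2:**
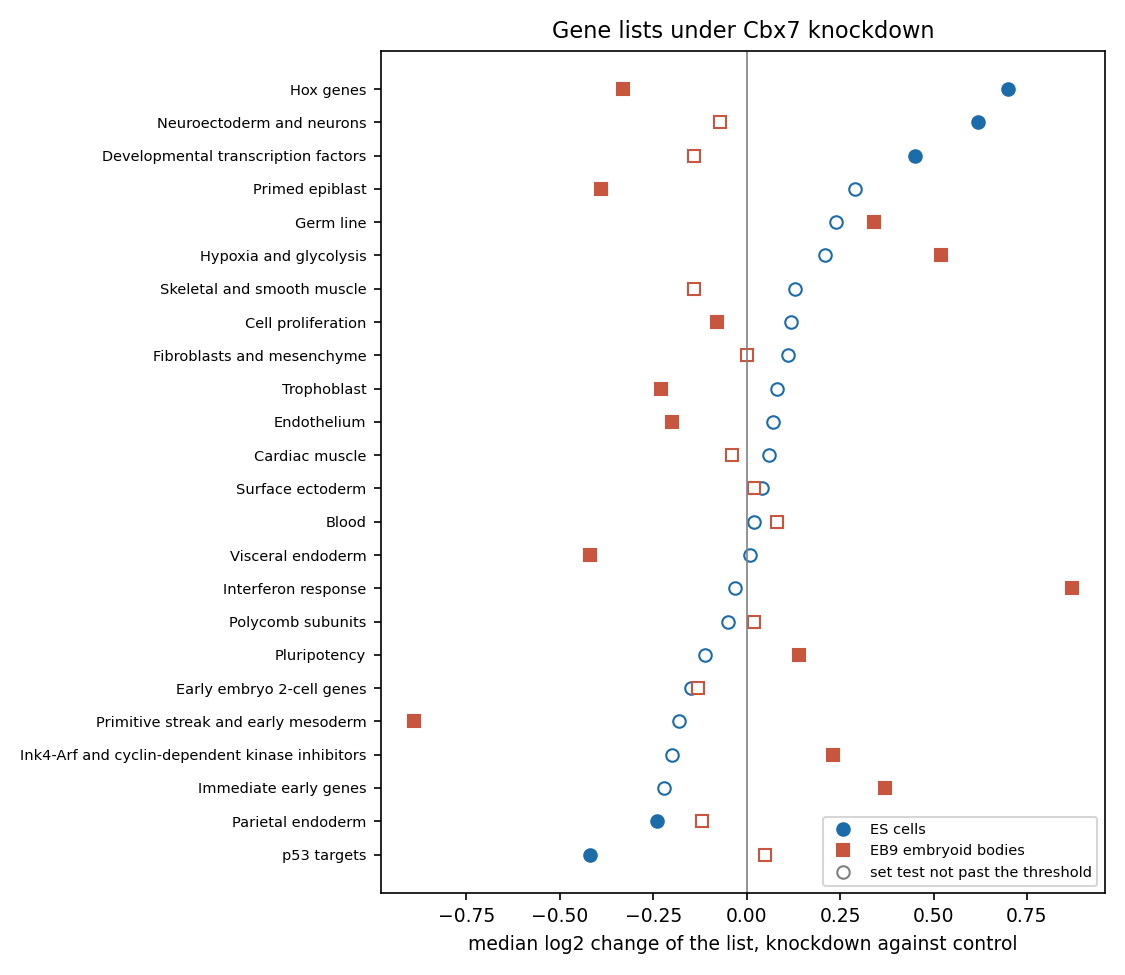
Median log2 change of each of the 24 gene lists, knockdown against control, in ES cells (circles) and in EB9 (squares); filled symbols passed the set test with the preset correlation. Hox genes lie at 0.7 in ES cells and at −0.33 in EB9, and the primitive streak list at −0.18 and −0.89.

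Both knockdown comparisons, which share no array, had 1707 genes past the threshold in common. Of these 551 were higher in both and 422 lower in both, where independent lists of these sizes would share 370.5 and 251.5. Another 424 were higher in ES cells and lower in EB9 (335.1 by independence) and 310 the reverse (278.1), so 57% of the shared genes moved the same way. Xlr4b fell in both, and so did Suz12 and Bmi1. Among genes changed at least 2-fold in each, 19 rose and 34 fell in both, against 2.6 and 4.5 by independence, while 7 rose in ES cells and fell in EB9 (2.5) and 7 the reverse (4.7). Across all genes the changes correlated at a Pearson r of 0.147 and a Spearman rho of 0.113, where genes are not independent replicates. Without the filter on dim probes r was 0.0227. With the slide term 3165 genes were shared, 1714 in the same and 1451 in opposite directions. Without EB9 knockdown 4 the counts were 562 and 415, without EB9 knockdown 3 621 and 421, and without EB9 control 4 641 and 439. Without the filter on dim probes they were 622 and 457.

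The difference of the knockdown effect between EB9 and ES cells was tested directly. Hox genes differed as a group (1 higher and 23 lower of 37 in EB9 relative to ES cells, 1 and 25 over the list alone, median −1.13, adjusted p = 1.87e-07; adjusted p = 0.11 with an estimated correlation). The effect on Hoxb6 was lower in EB9 by −2.41 (SE 0.3, adjusted p = 7.79e-05) and on Hoxa7 by −2.03 (SE 0.16, adjusted p = 3.53e-06). For T it was lower by −3.8 (SE 0.53, adjusted p = 0.00021) and for Ccnd2 by −3.11 (SE 0.1, adjusted p = 3.14e-09). For Meis2 it was higher by 2.21 (SE 0.14, adjusted p = 6.84e-07) and for Cdkn2b by 1.41 (SE 0.18, adjusted p = 0.000107). In all, 6292 genes differed, 2693 with a higher and 3599 with a lower effect in EB9, and 1134 by at least 2-fold, of which 674 had a higher and 460 a lower effect in EB9.

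The developmental transcription factors also differed (4 higher and 29 lower of 90, 4 and 32 over the list alone, median −0.54, adjusted p = 0.000284; adjusted p = 0.334 with an estimated correlation), with Neurod1 lower from signals that were near background in EB9 and Gata2 lower by −1.87 (SE 0.11). The counts over the list alone equalled those over all genes for the other lists that passed, except immediate early genes. They included neuroectoderm (0 higher and 9 lower of 24, −0.5, adjusted p = 0.0108; adjusted p = 0.501 with an estimated correlation), with Sox3 lower by −2.52 (SE 0.34). Higher effects in EB9 were found for immediate early genes (11 higher and 1 lower of 19, 12 and 2 over the list alone, 0.55, adjusted p = 0.000284; adjusted p = 0.11 with an estimated correlation) and p53 targets (9 higher and 1 lower of 19, 0.31, adjusted p = 0.000406; adjusted p = 0.0662 with an estimated correlation), both of which hold Btg2 (1.26, SE 0.09). They were also found for hypoxia and glycolysis (11 higher and 1 lower of 24, 0.32, adjusted p = 0.00117; adjusted p = 0.464 with an estimated correlation), with Pfkp at 1.21 (SE 0.15). Parietal endoderm differed too (4 higher and none lower of 12, 0.28, adjusted p = 0.0127; adjusted p = 0.392 with an estimated correlation), with Sparc at 0.78 (SE 0.09).

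Further lists passed the test of the difference with calls that hung on a setting or an array. Cell proliferation (1 higher and 14 lower of 32, median −0.18, adjusted p = 0.00918; adjusted p = 0.472 with an estimated correlation) was lost with quantile normalization (0.178) and with the authors' values (0.19). The interferon list (2 higher and 1 lower of 22, 0.9, adjusted p = 0.0127; adjusted p = 0.699 with an estimated correlation) was lost without EB9 knockdown 1 (0.0604) or EB9 control 2 (0.0592) and with fry (0.171). Pluripotency (11 higher and 4 lower of 32, 0.2, adjusted p = 0.0199; adjusted p = 0.699 with an estimated correlation) was lost without EB9 knockdown 2 (0.0979) or EB9 control 1 (0.059), with the mean of each gene's probes (0.0604), array weights (0.103) and fry (0.0879). Primed epiblast (1 higher and 7 lower of 12, −0.5, adjusted p = 0.0216; adjusted p = 0.444 with an estimated correlation) was lost without EB9 control 2 (0.0592), with normexp (0.074) and with the authors' values (0.0628). The Ink4-Arf list (4 higher and 1 lower of 7, 0.34, adjusted p = 0.0457; adjusted p = 0.334 with an estimated correlation) was lost without ES knockdown 1 (0.0575), ES control 3 (0.0503) or 4 (0.0633), EB9 knockdown 2 (0.083), or EB9 control 2 (0.075), 3 (0.0524) or 4 (0.0514). It was also lost with quantile normalization (0.0505), the authors' values (0.0628), the mean of each gene's probes (0.411) and array weights (0.0632).

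The primitive streak list did not pass the test of the difference (2 higher and 9 lower of 17, median −0.93, adjusted p = 0.122), although it did without EB9 knockdown 2 (0.0413) and with quantile normalization (0.0475), median scaling (0.0323), the authors' values (0.0236) and fry (0.0377). The Polycomb subunits did not pass either (5 higher and 4 lower of 32, adjusted p = 0.135) but did with quantile normalization (0.0475), without the filter on dim probes (0.0212) and with fry (0.0289). The effect on Suz12 was higher in EB9 by 0.41 (SE 0.09). The visceral endoderm list (adjusted p = 0.256) passed only without EB9 knockdown 2 (0.0152) among the settings tried. The other lists had adjusted p-values from 0.269 to 0.931, with blood at a median of 0.27 but tested downwards; of these only skeletal and smooth muscle passed with fry (0.0304). With the slide term 8682 genes differed, 6231 of the 6292 among them, median scaling gave 3929, array weights 10097 and slides 1 to 3 alone 4006. The count at 2-fold or more was 478 with normexp background correction, 479 with the authors' values and 1731 with array weights.

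The comparison of control EB9 with control ES cells describes differentiation without knockdown. Pluripotency genes fell (29 lower and 1 higher of 32, median −3.69), with Fgf4, a growth factor of the inner cell mass (chromosome 7, 152051089 to 152051148), lower by −5.96 (SE 0.11, n = 4 and 3, adjusted p = 2.59e-14). Markers of mesenchyme, endothelium, visceral endoderm, blood and the Hox genes rose. With an estimated correlation the adjusted p of these lists and of pluripotency lay between 0.0707 and 0.197. The collagen gene Col3a1 was at least 2750-fold higher and the extracellular matrix gene Postn at least 2140-fold. Embryonic globin Hba-x was at least 1660-fold higher and Hbb-bh1 rose by 12.07 (SE 0.31, adjusted p = 6.41e-13). In all, 15836 genes passed, 7043 higher and 8793 lower, and 8435 changed at least 2-fold, 3826 upwards and 4609 downwards.

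The counts adjusted over the list alone equalled those over all genes for every list in this and in the next comparison. Mesenchyme gave 20 higher and 1 lower of 21 (median 4.02, adjusted p = 1.71e-08; adjusted p = 0.152 with an estimated correlation), with Thy1 lower by −3.84. Endothelium gave 16 higher and 1 lower of 18 (3.41, adjusted p = 5.94e-08; adjusted p = 0.0707 with an estimated correlation), with the vessel adhesion molecule Cdh5 at least 263-fold higher and Fli1 at least 137-fold. Visceral endoderm gave 22 higher and 2 lower of 24 (4.04, adjusted p = 4.89e-07; adjusted p = 0.197 with an estimated correlation), with alpha-fetoprotein (Afp) at least 434-fold and transthyretin (Ttr) at least 209-fold higher. Blood gave 18 higher of 19 (3.87, adjusted p = 6.37e-07; adjusted p = 0.179 with an estimated correlation) and Hox genes 33 higher and 3 lower of 37 (3.77, adjusted p = 4.92e-09; adjusted p = 0.107 with an estimated correlation), with Hoxa11 at least 86.1-fold higher and Hoxc13 lower by −4.2. Cardiac muscle gave 17 higher and 7 lower of 26 (2.62, adjusted p = 0.00346; adjusted p = 0.233 with an estimated correlation), with cardiac actin (Actc1) at least 116-fold higher and Hand2 higher by 8.62 (SE 0.12). Developmental transcription factors gave 50 higher and 25 lower of 90 (1.5, adjusted p = 0.000112; adjusted p = 0.179 with an estimated correlation).

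Hypoxia and glycolysis gave 20 higher and 3 lower of 24 in control EB9 against ES cells (median 1.76, adjusted p = 2.83e-06), parietal endoderm 9 higher and 1 lower of 12 (1.68, adjusted p = 0.00101) and primed epiblast 9 higher and 2 lower of 12 (1.95, adjusted p = 0.00627). With an estimated correlation the adjusted p was 0.179 for each. The interferon list gave 14 higher and 4 lower of 22 (3.09, adjusted p = 0.0105; adjusted p = 0.589 with an estimated correlation). The lists that fell beside pluripotency (adjusted p = 3.06e-09; 0.179 as the adjusted p with an estimated correlation) were the 2-cell genes, all 12 lower (−5.46, adjusted p = 9.99e-06; adjusted p = 0.12 with an estimated correlation), the germ line, 17 of 20 lower (−3.33, adjusted p = 1.04e-05; adjusted p = 0.179 with an estimated correlation), and cell proliferation, 21 lower and 5 higher of 32 (−0.49, adjusted p = 0.0105; adjusted p = 0.321 with an estimated correlation), which was lost with median scaling (0.0695). Gtsf1, a factor of the piRNA pathway, fell by 8.16 (SE 0.13) and Stra8 fell by 7.32. Of the Polycomb subunits 13 were higher and 14 lower of 32, and they did not pass the set test (adjusted p = 0.995) but were lower with fry (7.19e-05). Phc1 fell by 2.45, Mtf2 fell by 2.04 and Suz12 fell by 1.3. Yaf2 rose by 2.21 and Cbx8, another chromodomain subunit of canonical complex 1, by 1.28 (SE 0.27). The adjusted p was 0.116 for primitive streak, 0.7 for skeletal and smooth muscle (median −0.23, mean 0.48), 0.525 for neuroectoderm (median −0.25, tested upwards) and for the Ink4-Arf list, 0.175 for surface ectoderm, 0.609 for trophoblast, 0.0577 for p53 targets and 0.0705 for immediate early genes. With fry each of these lists passed (0.0152 or lower). The p53 list passed with quantile normalization (0.0485), median scaling (0.0421), without the filter on dim probes (0.00638) and without ES control 3 (0.0495). With the slide term 17201 genes passed, and the changes within slides 1, 2 and 3 correlated with each other at 0.95 to 0.971 across all genes. The groups did not overlap for 73% of all genes (5.7% by chance). The median change of all genes was −0.141 and depended on the scaling: it was 0.015 with median scaling and 0.114 without the filter on dim probes.

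Knockdown EB9 against knockdown ES cells describes the same differentiation in cells that carry the hairpin. Pluripotency genes fell (29 lower and 1 higher of 32, median −3.38, adjusted p = 1.22e-08; adjusted p = 0.196 with an estimated correlation), with Fgf4 at −5.93 (SE 0.1, n = 4 and 4, adjusted p = 1.24e-14). Col3a1 was at least 3070-fold and Postn at least 2490-fold higher, Hba-x at least 1900-fold, and Hbb-bh1 rose by 12.4 (SE 0.29). Afp was at least 453-fold and Ttr at least 128-fold higher. In all, 16503 genes passed, 7147 higher and 9356 lower, and 8827 changed at least 2-fold, 3908 upwards and 4919 downwards.

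The lists that rose in knockdown EB9 against knockdown ES cells were mesenchyme (19 higher and 1 lower of 21, median 3.7, adjusted p = 8.17e-08), endothelium (16 and 1 of 18, 2.88, adjusted p = 1.09e-07), hypoxia and glycolysis (21 and 1 of 24, 1.75, adjusted p = 1.82e-07), Hox genes (32 and 4 of 37, 2.55, adjusted p = 4.96e-07), visceral endoderm (21 and 3 of 24, 3.84, adjusted p = 2.66e-06) and blood (15 and 0 of 19, 3.73, adjusted p = 6.43e-06). With an estimated correlation their adjusted p was 0.126, 0.0752, 0.142, 0.126, 0.238 and 0.238. Parietal endoderm (10 and 0 of 12, 2.33, adjusted p = 0.000132), the interferon list (15 and 2 of 22, 4.28, adjusted p = 0.000635), immediate early genes (13 and 3 of 19, 0.39, adjusted p = 0.000901), cardiac muscle (17 and 5 of 26, 2.3, adjusted p = 0.00104) and developmental transcription factors (45 and 30 of 90, 0.39, adjusted p = 0.00423) rose as well, at 0.126, 0.452, 0.126, 0.238 and 0.275 as the adjusted p with an estimated correlation. Primed epiblast (8 and 4 of 12, 1.48, adjusted p = 0.0339; adjusted p = 0.28 with an estimated correlation) was lost with quantile normalization (0.0543), with array weights (0.0632) and without EB9 knockdown 2 (0.0534). The 2-cell genes (12 lower of 12, −5.47, adjusted p = 1.71e-05; adjusted p = 0.126 with an estimated correlation), the germ line (17 lower and 1 higher of 20, −3.47, adjusted p = 1.86e-05; adjusted p = 0.235 with an estimated correlation) and cell proliferation (24 lower and 3 higher of 32, −0.63, adjusted p = 0.000635; adjusted p = 0.238 with an estimated correlation) fell. Jun rose by 3.74 and Egr1 fell by 0.67, Gtsf1 fell by 7.09 and the minichromosome maintenance gene Mcm2 by 1.26. The Polycomb subunits gave 15 higher and 15 lower of 32 (adjusted p = 0.736), with Phc1 lower by −2.39, Yaf2 higher by 2.22 and Cbx8 higher by 1.74. The adjusted p was 0.501 for primitive streak, 0.94 for skeletal and smooth muscle (median −0.69, mean 0.33) and for trophoblast (−0.3 and 0.67), 0.759 for neuroectoderm and for the Ink4-Arf list (0.09 and −0.04 for the latter), 0.182 for surface ectoderm and 0.332 for p53 targets. With fry these lists passed (0.0429 or lower) and the Polycomb subunits did not (0.0511). With the slide term 18008 genes passed, and the changes within the 4 slides correlated with each other at 0.955 to 0.975 across all genes. The groups did not overlap for 74.2% of all genes (2.9% by chance). The median change of all genes was −0.183, and quantile normalization or the authors' values moved it to −0.081 or −0.058.

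**Figure D3:**
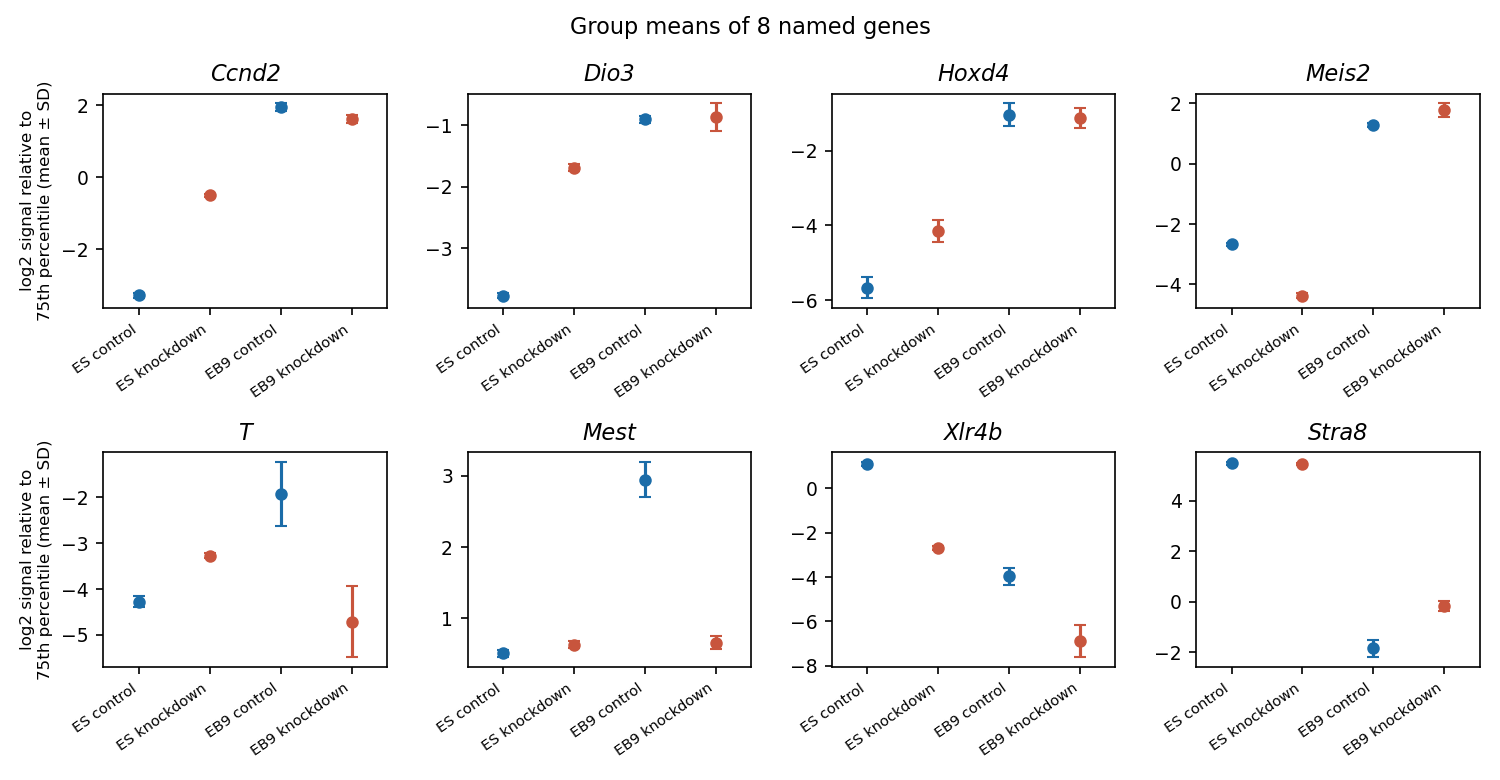
Mean and SD (bars) of the log2 signal relative to the 75th percentile of the array for 8 named genes in the 4 groups (n = 3 for control ES cells, n = 4 for the others). Ccnd2 was higher in knockdown than in control ES cells, T and Mest were lower in knockdown than in control EB9, and Xlr4b was lower with knockdown in both.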

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

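The tests of a culture batch carried by the replicate number, of the loss of an X chromosome and of differentiated or neural cells in the knockdown ES cultures and the regrouping within slides were chosen only after the results were seen.

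The arrays' deviations from their group means parted slides 1 and 4 from slides 2 and 3, since the mean correlation across genes was 0.37 between arrays of different groups within a pair of slides and −0.37 across pairs. The deviations of slides 1 to 4 followed probe GC content (Spearman's correlation 0.23, −0.15, −0.16 and 0.09) and signal level (0.19, −0.26, −0.18 and 0.34), with signs that part the same pairs. Both are argued against as the whole cause: centring within bins of GC cut the strongest of the GC correlations to 0.05 and left the difference of the mean correlations at 0.75, and centring within bins of level (0.03) left it at 0.72. The 3 ES controls, as the labels number them, lay on slides of other numbers. They correlated at a median of −0.34 with their own number (9 pairs, −0.59 to 0.37). ES controls 2 and 4 (−0.59 to −0.3) argue against a culture batch carried by the replicate number. ES control 3 (0.36 to 0.37) cannot decide, since its slide and the slide of its number belong to the same pair. If the numbers of the ES controls were shifted by 1, slide and number would be the same and this batch would stay open. Steps shared by the arrays of a slide, such as labelling, hybridisation and scanning, may account for the pattern and were not tested, nor was a biological explanation.

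X-linked genes made up more of the falls in knockdown ES cells than autosomal ones: 74 of 884 (8.37%) fell at least 2-fold, against 575 of 20131 (2.86%, odds ratio 3.11, two-sided Fisher's exact p = 5.5e-15 with genes taken as independent). Loss of an X chromosome would lower most X-linked genes, but their median change was 0.104 (quartiles −0.219 and 0.343), and a trend on probe GC content and signal level is argued against by the 97.3% of these falls that stayed at least 2-fold once it was removed. Neighbouring copies of gene families could inflate the count, since 9 of the 74 are Xlr genes. Counting each 1 Mb window once gave an odds ratio of 1.23 (95% confidence interval 0.802 to 1.84, two-sided Fisher's exact p = 0.341), which leaves this open. A window counted if it held any fall, and X windows held fewer genes (884 in 144 windows, against 20131 in 2141 autosomal ones). This lowers the odds ratio and was not adjusted for. Of 24 of these genes measured on every EB9 control array 10 (41.7%) were also lower in knockdown EB9, against 54 of 320 autosomal falls (16.9%), which leaves open a difference between control and knockdown cells that persists through differentiation. Neighbouring copies could inflate the X-linked share here too, since each gene was counted singly. An effect of the hairpin through Cbx7 stays open as well, untested apart from other differences between control and knockdown cells.

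Hox genes rose in knockdown ES cells (median 0.7) and fell in knockdown EB9 (−0.33), calls that were lost with an estimated correlation (adjusted p = 0.463 and 0.151). Probes near background are argued against in ES cells, where the 19 of 37 members well above background on all 15 arrays had a median of 0.72. In EB9 these members had a median of −0.2 and 5 of them were lower. This leaves such probes undecided as an account of the fall in EB9, since the filter also drops members that are dim only in ES cells. The list kept its EB9 call with normexp background correction and with the authors' values. Removing the trend on probe GC content and signal level left medians of 0.74 and −0.37, which argues against that trend at both stages. Parietal endoderm markers fell in the knockdown ES cultures (median −0.24, set test adjusted p = 0.00565, or 0.463 with an estimated correlation). This fall was known when the test for differentiated cells of all lineages was chosen, so it cannot decide against such cells. Neural cells stay open as well. The neuroectoderm and neuron list rose (14 higher and 1 lower of 24, median 0.62, set test adjusted p = 0.00565, or 0.748 with an estimated correlation). Its 12 members on neither the Hox nor the developmental transcription factor list had a median of 0.56, with 6 higher and 1 lower. An effect of reduced Cbx7 stays open as a hypothesis in ES cells. Probe A_55_P1980401 was lower there past the threshold only with the slide term (−1.41, SE 0.17). Probe A_55_P1980408, well above background on every ES array, differed by −0.03 (SE 0.13) with that term. In EB9 neither Cbx7 probe showed a reduction past the threshold. Probe A_55_P1980401 was well above background on only 2 of 4 arrays of each EB9 group. Probe A_55_P1980408, well above background on every EB9 array, differed by −0.16 (SE 0.22). A reduction in EB9 was thus neither shown nor ruled out. An effect in EB9, present there or carried over from an earlier stage, thus stays a hypothesis. With 1 hairpin no such effect was tested apart from other differences between control and knockdown cells.

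Only the real split gave the gene count in regroupings that exchange arrays freely, slides included. The counts were 8147 genes in ES cells (35 splits, highest other 2076) and 3211 in EB9 (2954). They were 15836 for control EB9 against ES cells (13254), 16503 with knockdown (1) and 6292 for the difference of the effect (100 splits, 4299). A share of 1 in 35 lies under 0.05 but is the lowest that 35 splits can give, so it argues against chance only weakly. In EB9 another split came close to the real count. It was the real split with EB9 knockdown 2 and EB9 control 1 exchanged, and without EB9 knockdown 2 the real split gave 4393 genes. The splits with 2076 and 13254 genes also differed from the real ones by only 1 array exchanged or moved. These 3 counts therefore keep much of the real contrast and are not levels given by chance alone. Every other split of the knockdown stage comparison mixed the stages, which the first principal component (87.2% of the variance) parts. Its low counts therefore decide nothing. For the 973 genes changed the same way at both stages these splits decide nothing, since 98 of the 99 others shared no gene (highest other 1). The EB9 split that parts slides 1 and 4 from slides 2 and 3 gave 1640 genes. Swapping arrays only within slides leaves 8 splits, too few for a share under 0.05: the highest other was 11 in ES cells, 48 in EB9, 11784 for control EB9 against ES cells and 1 with knockdown. With the slide as a block the real counts and highest others were 10058 and 5275, 5663 and 56, 17201 and 14401, and 18008 and 0, and 5275 and 14401 come from the split that exchanges the groups on all of slides 1 to 3 and leaves the unpaired array in place. Chance cannot be excluded for the number of lists past the set test: 7 of 35 splits gave at least the 5 lists of ES cells (highest other 5), 2 the 13 of EB9 (13), 6 the 15 of control EB9 against ES cells (16), 3 the 16 with knockdown (16), and 6 of 100 the 12 of the difference of the effect (13). In the first 4 comparisons each other split that reached the real number had only 1 array exchanged or moved. Such a split keeps much of the real contrast, so it is a poor measure of chance. With 2 arrays exchanged the highest numbers of lists were 3, 12, 14 and 4.

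The knockdown effect differed between EB9 and ES cells for 6292 genes. Of the 86 genes named for the comparisons 58 were among them. The effect in EB9 was lower for Alcam (−1.69), Alox15 (−2.67), Bax (−0.53), Ccnd2 (−3.11), Cdkn1c (−1.49), Cer1 (−2.95), Dio3 (−2.06), Etv2 (−1.22), Fgf15 (−2.22), Gata2 (−1.87), Gbp2 (−0.98), Hand2 (−1.09), Hoxa11 (−1.54), Hoxa7 (−2.03), Hoxb6 (−2.41), Hoxb9 (−1.44), Hoxd4 (−1.62), Jun (−0.5), Mcm2 (−0.54), Mest (−2.4), Neurod1 (−1.97), Olig2 (−1.72), Pax1 (−3.52), Plk1 (−0.29), Pou3f2 (−3.1), Prdm8 (−1.41), Rhox6 (−1.91), Sox3 (−2.52), T (−3.8), Tbx3 (−0.65), Thy1 (−0.8), Twist2 (−3.09) and Zic1 (−0.97). It was higher for Afp (1.28), Ankrd37 (0.62), Bfsp2 (4.12), Btg2 (1.26), Ccng1 (0.9), Cdkn2b (1.41), Col4a1 (0.54), Dnajc5g (3.72), Egr1 (0.55), Gtsf1 (1.07), Ier3 (0.91), Jarid2 (0.48), Junb (0.95), Meis2 (2.21), Nts (1.66), Olfr1466 (4.31), Pfkp (1.21), Phlda3 (0.81), Rybp (0.38), Sparc (0.78), Stmn4 (1.4), Stra8 (1.71), Suz12 (0.41), Xlr3b (1.31) and Xlr5b (2.78). For 13 of these genes at least 1 of the 4 groups had no array well above background, so their values are not exact sizes. Over the settings tried they ran from 0.14 to 1.42 for Afp, −1.93 to −0.38 for Alcam, 1.96 to 4.42 for Bfsp2, −3.39 to −0.69 for Cer1, 1.22 to 4.15 for Dnajc5g, −1.77 to −0.52 for Hoxa11, −2.12 to −0.55 for Neurod1, 0.94 to 1.93 for Nts, −2.08 to −0.47 for Olig2, −3.62 to −1.03 for Pax1, −3.66 to −0.86 for Pou3f2, −1.71 to −0.06 for Prdm8 and −3.37 to −0.65 for Twist2. Another 10 moved more than 1.5 times: Alox15 (−3.03 to −1.02), Gbp2 (−1.1 to −0.06), Hand2 (−1.25 to −0.53), Hoxb6 (−2.59 to −1.49), Hoxb9 (−1.62 to −0.89), Hoxd4 (−2.17 to −0.81), Junb (0.62 to 1.17), Plk1 (−0.36 to −0.12), Xlr3b (1.03 to 2.14) and Zic1 (−1.13 to −0.05). Apart from stricter thresholds, 42 of the 58 kept this call in every setting tried. With normexp background correction and with the authors' values the call was lost for Gbp2 (−0.23 and −0.06), Afp (0.14 and 0.42), Alcam (−0.54 and −0.38), Prdm8 (−0.21 and −0.06) and Zic1 (−0.2 and −0.05). It was lost in 12 of 26 settings for Jarid2 (0.4 to 0.59), in 17 for Plk1, in 18 for Tbx3 (−0.81 to −0.47) and in 6 for Olig2. Median scaling ended it for Ankrd37, Col4a1, Egr1, Jun and Rybp, and slides 1 to 3 alone for Bax, Jun, Xlr3b and Zic1. Zic1 also lost it without ES control 2 (−0.87).

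The list medians of this difference, for lists past its set test, were −0.5 for primed epiblast, −0.5 for neuroectoderm and neurons, −1.13 for Hox genes, −0.54 for developmental transcription factors, −0.18 for cell proliferation, 0.2 for pluripotency, 0.28 for parietal endoderm, 0.34 for the Ink4-Arf list, 0.31 for p53 targets, 0.9 for the interferon response, 0.55 for immediate early genes and 0.32 for hypoxia and glycolysis. With an estimated correlation none of them passed (adjusted p from 0.0662 to 0.699). The calls of cell proliferation, the interferon response, pluripotency, primed epiblast and the Ink4-Arf list were lost in other settings as well.

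Among 276 groups of 4 arrays checked, over the named genes, both Cbx7 probes and the quality values, 24 held an array far from the other 3, where chance gives about 1 in 20. In knockdown ES cells these were Actc1 (−8.9), Afp (−8.72), Cdh5 (−4.75) and Srgn (−2.58) on replicate 3, Btg2 (−1.21) on replicate 2, Olig2 (−4.46) and Tbx3 (4.08) on replicate 1 and Stmn4 (−4.97) on replicate 4. In control EB9 they were Afp (2.2), Ankrd37 (2.96), Etv2 (−0.57) and Oas1a (0.68) on replicate 1 and Xlr3b (−2.55) on replicate 2, which also had the highest mean of the negative controls (42.88). In knockdown EB9 they were Cer1 (−7.98) on replicate 3, Hbb-bh1 (6.61), Hoxb9 (−4.89), Plk1 (3.72), Srgn (−1.78) and Xlr4a (−5.76) on replicate 2, and Hoxa11 (−0.54), Hoxc13 (−7.03), Olig2 (−6.24) and Prdm8 (−4.39) on replicate 1.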

How the results depend on the processing

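The fit of slides 1 to 3 alone and the slide block together with a 2-fold minimum were chosen only after the slide effect was seen.

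The counts of genes for both stage comparisons kept within 1.5 times their value in every setting other than the 2-fold minimum, and the count for ES cells in every setting other than that minimum and array weights. The EB9 count and the overlap depended most on the setting, and the cause was not tested unless the setting itself gives it (fewer arrays or a stricter threshold). Signal over background limits Cbx7 probe A_55_P1980401 and the bounds given as "at least". With the replicate number as a block, which the pairing check did not bear out, probe A_55_P1980401 of Cbx7 differed by −1.43 in ES cells; among the lists and named genes this block cost trophoblast in EB9 (adjusted p = 0.0607) and Mki67 in the difference of the effect (0.24 in log2 change), and it gained skeletal and smooth muscle in EB9 (adjusted p = 0.0359).

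Median scaling gave 1398 genes in EB9, 3929 for the difference of the effect and 371 and 215 genes changed in the same and in opposite directions at both stages. The authors' values gave 479 in opposite directions, and Rybp in the knockdown stage comparison turned to 0.08 (0.04 with quantile normalisation). Without the filter on dim probes the overlap was 622 and 457. With the mean of each gene's probes Rbbp4 turned to −0.31 in ES cells and to 0.2 in the difference of the effect, Cdkn1a to −0.12 in the latter, and Vwf to 0 in the control stage comparison. A fit of the compared groups alone gave 1133 genes in EB9 and an overlap of 388 and 243.

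The slide block gave 5663 genes in EB9, an overlap of 1714 and 1451, and −1.41 for Cbx7 probe A_55_P1980401 in ES cells, now past the threshold. Array weights gave 14011 genes in ES cells, 6481 in EB9, 10097 for the difference and an overlap of 2730 and 1942, while 8 lists passed in EB9. An adjusted p under 0.01 left 1262 genes in EB9, 3913 for the difference and an overlap of 333 and 223. A 2-fold minimum left 1039 genes in ES cells, 294 in EB9, 8435 and 8827 in the control and knockdown stage comparisons, 1134 for the difference and an overlap of 53 and 14; with the slide block as well these were 1030, 325, 8447, 8889, 1252, 56 and 18. Slides 1 to 3 alone gave 674 genes in EB9, 4006 for the difference and an overlap of 212 and 120. With an estimated correlation, taken from the fit without a slide term, 0 lists passed in each of the 5 comparisons. The other test, fry, gave 9 in ES cells and 24 in the control stage comparison.

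Leaving out 1 array at a time, the EB9 count ranged from 1807 (without EB9 knockdown 4) to 4393 (without EB9 knockdown 2), the overlap in the same direction from 562 to 1342 and in opposite directions from 415 to 1031, with the same arrays left out. The counts ranged from 6489 to 8558 in ES cells, from 15062 to 15928 and 16058 to 16641 in the control and knockdown stage comparisons and from 5270 to 6750 for the difference. Between 10 and 14 lists passed in EB9 and between 9 and 12 for the difference.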

Other observations

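Whole chromosomes differed slightly in knockdown ES cells. The 824 genes of chromosome 14 had a median log2 change of 0.138 (0.159 with the slide term), those of chromosome 12 0.091 and those of chromosome X 0.104, while the medians of the other chromosomes lay between −0.006 and 0.058. In EB9 the median of chromosome 14 was −0.015. These medians were looked at after the results were seen and were not tested.

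A hypothesis was that knockdown ES cells were shifted towards the expression of EB9. Of the 1039 genes changed at least 2-fold in knockdown ES cells, 567 (54.6%) changed the same way from knockdown ES cells to control EB9, a comparison that the shared ES arrays bias against the hypothesis, and 766 (73.7%) did so from control ES cells, which bias towards it. Of all genes 43.2% and 44% were higher in EB9 from these starts. From knockdown ES cells 187 of 373 rises (50.1%) and 380 of 666 falls (57.1%) changed the same way. The share of the falls lay close to the share of all genes that were lower in EB9. The value lies between the bounds set before the test, so a shift may be present and these data leave it open.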
